A study of Homo sapiens with 16 samples.

How the data were processed

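The authors profiled 2 established EBV-positive gastric cancer cell lines, SNU719 and YCC10, by RNA-seq after lowering MYB or TCF7. Their notes give 1 ug of total RNA per library and the TruSeq Stranded mRNA kit, which selects polyadenylated RNA. SNU719 was grown in RPMI1640 and YCC10 in EMEM. According to the same notes reads were converted with bcl2fastq 2.20.0, aligned to hg38 with HISAT2 2.1.0 and quantified with Cufflinks 2.2.1. Settings of these tools and the gene annotation are not given in the sources used here. Raw reads were not used here.

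The values deposited by the authors are FPKM, fragments per kilobase of transcript scaled to the mapped fragments of the library, in 1 table of 33648 rows and 16 libraries. The table held 0 columns of other samples. FPKM carries no fragment counts, so the sequencing depth of a library is unknown. A relative depth was estimated from the lowest values listed in each library; it ranged from 0.603 to 1.3 times that of the first YCC10 siCtrl library of the MYB set. Of the 28167 gene symbols, 2097 stood on more than 1 row (7578 rows), and the rows of 1 symbol were summed. Of the symbols, 95.5 percent occur among RefSeq names.

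The libraries form 12 groups in 3 sets. The MYB set holds siCtrl and siMYB, 2 libraries each per line. The TCF7 set holds siCtrl and siTCF7, 1 library each per line. The CRISPRi set holds sgCtrl and sgMYB-E3, a guide for CRISPR interference at an enhancer of MYB, 1 library each per line. Each set has its own controls. Nothing in the sources used here says that libraries of 1 group come from separate cultures, so the spread between them may be technical. The MYB-set libraries numbered 1 differ from the others: of 263 short RNA genes reaching 100 FPKM in some library they list 68.8 to 74.1 percent at 0, against 37.6 to 57.4 percent in the other 12. Whether the numbers pair the samples was checked by the correlation of replicate differences between groups. It was 0.342 and 0.438 within a line and 0.326 to 0.411 across lines. The number thus marks a difference shared by all groups of the set, not only by pairs within a line. The main fits leave the number out. A fit with a block for each pair of same-numbered libraries within a line and set is given where it changes a call or moves a count by more than 1.5 times. No fit used the number as 1 term shared by all groups.

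Tests used limma 3.58.1 (lmFit and eBayes with an intensity trend) in R 4.3.3 on log2(FPKM + 1), for genes with a mean of at least 1 FPKM over the libraries of the fit. P-values were adjusted by the Benjamini-Hochberg method and the threshold was 0.05. The MYB set was fitted with 4 group means (4 residual degrees of freedom), which gave siMYB against siCtrl in each line and the difference of both effects. A second fit with the cell line as covariate gave siMYB over both lines (5 degrees of freedom). The effects of siTCF7 and sgMYB-E3 came from a fit of all 16 libraries with a term for each pair of line and set (6 degrees of freedom). In that fit siTCF7 and sgMYB-E3 each have 1 effect shared by both lines. A difference between the lines in either effect enters the shared spread and the p-values of both. The fit assumes that these single libraries vary as the MYB-set libraries do. The same fit compared the mean siMYB effect with the sgMYB-E3 effect and with the siTCF7 effect. The control libraries of both lines, 4 per line, were compared with the set as covariate (4 degrees of freedom). Within a line, siTCF7 and sgMYB-E3 have 1 library per group and no test.

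A log2 fold change on log2(FPKM + 1) understates the change of weakly expressed genes. A value listed at exactly 0 is given as listed, without a fold change for that line. Values after a plus-minus sign are standard deviations of 2 libraries; errors of log2 changes are standard errors (SE) from limma.

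Fixed in advance were 27 gene lists: the MYB family, the TCF/LEF family, known MYB targets, WNT targets, G1/S and replication genes, G2/M and mitosis genes, MYC-driven and nucleolar ribosome biogenesis genes, p53 targets, apoptosis regulators, the integrated stress and unfolded protein responses, interferon genes, NF-kB inflammation genes, antigen presentation, mesenchymal genes of the epithelial-mesenchymal transition, epithelial genes, gastric markers, intestinal markers, stem markers, lymphoid genes, fibroblast and endothelial genes, hypoxia and glycolysis, cholesterol synthesis, oxidative phosphorylation, ribosomal proteins, mitochondrially encoded genes, non-polyadenylated histones and immediate early genes. A list with at least 5 tested members was tested with camera at its preset correlation of 0.01, and again with an estimated correlation. That gave 22 tested lists in the fits of the MYB set. Members past the threshold were counted after adjustment over all genes and after adjustment over the list alone.

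Genes are named by a rule written before the data were examined. MYB and TCF7 are always given. In each comparison up to 10 genes with the largest rise and 10 with the largest fall past the threshold follow, where every knockdown library lies on one side of its controls. Where fewer than 10 genes pass, the 10 with the lowest p are eligible and said not to pass. Up to 4 passing members of each list follow, or 2 where the list passes and no member does. Left out are rows without a symbol, symbols on several rows, XIST and Y-linked genes, microRNA, snoRNA and similar short RNAs, and mitochondrial tRNAs. Genes within 1 Mb of MYB were taken from GENCODE v29 on GRCh38. Among eligible genes, those that kept their call in most alternative fits were preferred in the text. Results of some eligible genes are not reported here.

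Correlations of effects were computed across genes; genes are not independent replicates, so no p is given. Matches to siRNA seeds were searched by relating each 7-mer of the 3' UTR to the fold changes of 10657 genes with a 3' UTR of at least 50 bases in the annotation. The relation was adjusted for UTR length, GC content and mean expression. A 7-mer was kept if it passed Bonferroni correction (absolute t above 4.667), ranked among the 10 most negative in both lines of that siRNA and ranked outside the 100 most negative in both lines of sgMYB-E3. The siRNA and guide sequences are not given in the sources used here.

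Alternatives chosen before the data were examined were pseudocounts of 0.1 and 5, no expression filter, a filter of 5 FPKM, median-of-ratios scaling, quantile normalization and no intensity trend. Further ones were each library left out in turn, the block of same-numbered pairs (replicate block), only the 4 libraries of a set, and all 16 libraries for siMYB. For correlations they also included Spearman correlation and only called genes. Chosen after seeing the data were only symbols on 1 row, no short RNA genes, only the MYB-set libraries numbered 2, only genes without the 7-mers of an siRNA, scaling in the list tests, and each library left out in turn for SGK1, HBS1L and AHI1. In a fit without 1 library, a group left with 1 library was assumed to vary as the other groups do. Without 1 library of the TCF7 or CRISPRi set, the effect of that knockdown is its effect in the other line alone. Leaving out the knockdown or its control therefore gives the same value.

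Calls were also counted after splitting the libraries into other groups of equal size. The code was tested on simulated data, in which it found 88 percent of 2-fold changes and 54 percent of 1.5-fold changes for siMYB in SNU719, and 87 and 44 percent for sgMYB-E3. The simulated null lists gave 0 calls of 20. The simulated genes varied independently of each other, so this does not check the list tests for correlated genes. Short RNA genes are subject to poly(A) selection and fragment size and are not interpreted. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and jsonlite 2.0.0 in R.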

Results

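RNA-seq of polyadenylated RNA was measured in SNU719 and YCC10, 2 EBV-positive gastric cancer cell lines. The 16 libraries form 12 groups in 3 sets, each with its own controls. The MYB set compares siMYB with siCtrl (n = 2 libraries per group and line), the TCF7 set siTCF7 with siCtrl (n = 1 per group and line), and the CRISPRi set sgMYB-E3 with sgCtrl (n = 1 per group and line). The deposited values are FPKM, so the depth is unknown; relative depth ranged from 0.603 to 1.3. Between 11176 and 12085 genes reached 1 FPKM per library. Replicate libraries of the MYB set correlated at 0.9936 to 0.9943 on the log scale. The p-values below measure only the spread between these samples, which may be technical because nothing says they come from separate cultures. For siTCF7 and sgMYB-E3 that spread comes from the MYB-set replicates and from the line differences of both effects. Their p-values assume that the single libraries vary as the MYB-set ones do. The 4 MYB-set libraries numbered 1 stand apart in short RNA genes (68.8 to 74.1 percent of 263 listed at 0, against 37.6 to 57.4 percent in the other 12). Replicate differences correlate between all groups of the set (0.326 to 0.438, and 0.534 to 0.716 without short RNA genes). Groups with a single library have no replicates, so no p exists for siTCF7 or sgMYB-E3 within a line.

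MYB (ENSG00000118513.18, chr6:135181315-135219173, plus strand) encodes a DNA-binding activator of proliferation genes in progenitor cells. With siMYB its level was 9.06 ± 0.857 against 44.95 ± 1.03 FPKM in SNU719 (20.2 percent of control) and 1.687 ± 0.369 against 28.35 ± 1.43 FPKM in YCC10 (5.95 percent; n = 2 per group). With siTCF7 it was 25.27 against 45.12 FPKM in SNU719 (56 percent) and 5.396 against 25.56 FPKM in YCC10 (21.1 percent; n = 1 per group). With sgMYB-E3 it was 18.34 against 47.64 FPKM in SNU719 (38.5 percent) and 12.33 against 21.11 FPKM in YCC10 (58.4 percent; n = 1 per group). MYB fell by 2.83 log2 units over both lines with siMYB (SE 0.251, adjusted p = 0.00137) and fell by 1.43 with siTCF7 (SE 0.264, adjusted p = 0.0113). In SNU719 alone, which is what a fit without either YCC10 library of the TCF7 set leaves, the siTCF7 value was -0.81. In YCC10 alone it was -2.05. The sgMYB-E3 value of -1.03 (SE 0.264) did not pass (adjusted p = 0.981), with -1.33 in SNU719 alone and -0.73 in YCC10 alone. Both knockdowns share 1 spread in this fit, so the line difference of siTCF7 also enters this SE and p.

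TCF7 (ENSG00000081059.19, chr5:134114711-134151865, plus strand) encodes TCF-1, a partner of beta-catenin in WNT signaling. With siTCF7 its level was 7.993 against 26.94 FPKM in SNU719 (29.7 percent) and 4.143 against 22.64 FPKM in YCC10 (18.3 percent; n = 1 per group). TCF7 fell by 1.92 log2 units over both lines (SE 0.127, adjusted p = 0.000624). With siMYB it was 18.68 ± 0.158 against 22.58 ± 2.33 FPKM in SNU719 (82.7 percent) and 15.37 ± 1.21 against 15.96 ± 0.136 FPKM in YCC10 (96.3 percent; n = 2 per group), which did not pass over both lines (-0.16, adjusted p = 0.152). With sgMYB-E3 it was 25.64 against 24.52 FPKM in SNU719 (105 percent) and 21.71 against 20.79 FPKM in YCC10 (104 percent; n = 1 per group; adjusted p = 1). Thus MYB was lower in all 3 kinds of knockdown, and TCF7 fell only with its own siRNA.

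**Figure D1:**
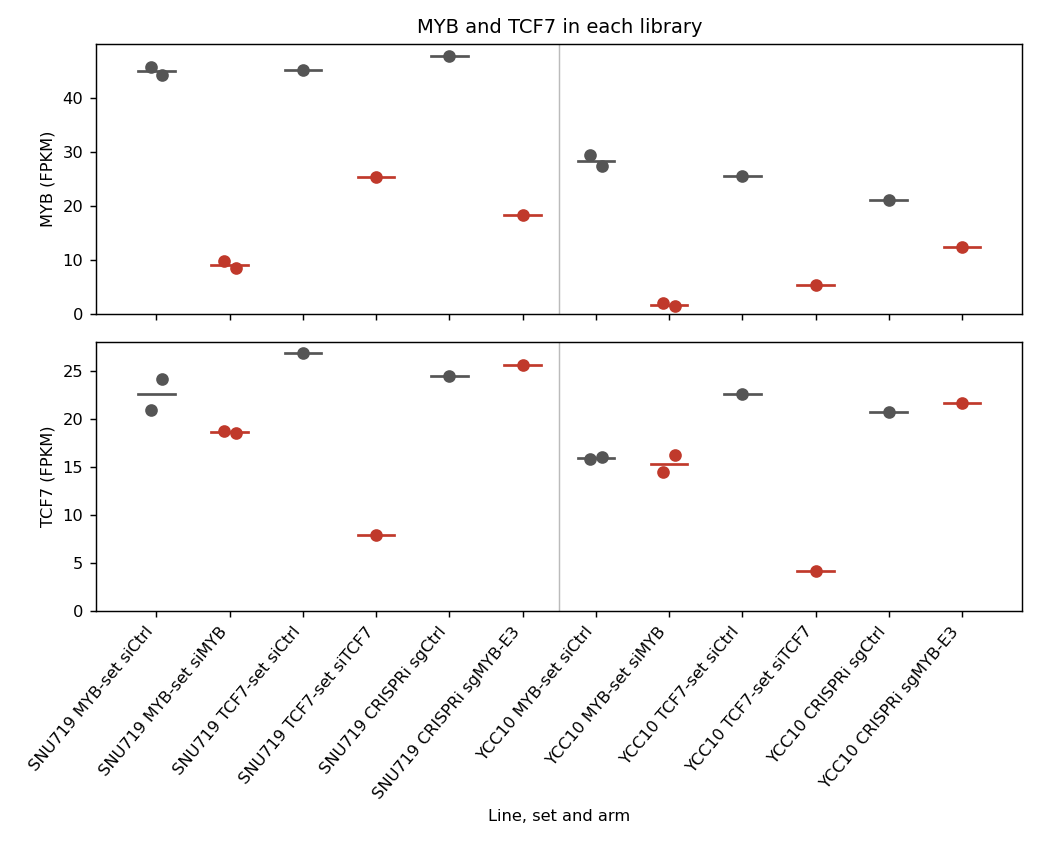
MYB and TCF7 in every library in FPKM, controls in grey and knockdowns in red. Each dot is 1 library and each line a group mean.

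The first question near these targets is whether neighboring genes and relatives moved with them. Of 10 genes within 1 Mb of MYB, 5 reached 1 FPKM. HBS1L, next to MYB and encoding a ribosome rescue factor, fell over both lines with siMYB (-0.45, adjusted p = 0.0101) and gave -0.11 with sgMYB-E3 (adjusted p = 1). SGK1, encoding a serum- and glucocorticoid-induced kinase, rose with siMYB in SNU719 (0.66, SE 0.0572, adjusted p = 0.00176) and YCC10 (1.25, adjusted p = 0.000152), and with siTCF7 (0.67, SE 0.0782, adjusted p = 0.00345). It gave 0.15 with sgMYB-E3 (adjusted p = 1). AHI1, encoding a cilium protein, gave -0.32 with siMYB in YCC10 (adjusted p = 0.0168), a call lost without YCC10 siCtrl 1 (0.079), siCtrl 2 (0.0567) or siMYB 2 (0.0722). It gave -0.44 with siTCF7 over both lines (adjusted p = 0.0302), a call lost without any 1 CRISPRi library (0.0524 to 0.0525). In SNU719 alone the siTCF7 value of AHI1 was -0.17. In YCC10 alone AHI1 gave -0.70 with siTCF7, and with sgMYB-E3 over both lines it gave -0.01 (adjusted p = 1). The family member MYBL2, which drives mitotic genes, fell with siMYB (-0.95, SE 0.113, adjusted p = 0.00266) and with siTCF7 (-1.62, SE 0.292, adjusted p = 0.0108). In SNU719 alone the siTCF7 value of MYBL2 was -0.84. With sgMYB-E3 MYBL2 gave -0.05 (SE 0.292) and did not pass. In the TCF/LEF family, TCF7L2, another partner of beta-catenin, gave 0.34 with siMYB over both lines (adjusted p = 0.0434), a call lost with the replicate block (0.0779) and without any 1 of the 8 libraries (0.0542 to 0.105). It gave 0.41 with siTCF7 over both lines (adjusted p = 0.0224), and only 0.26 in SNU719 alone, which 1 library per group cannot test.

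The next question is which genes change with siMYB in SNU719. SPRR3, a cornified envelope protein of squamous epithelium, rose from 0.4594 ± 0.231 to 18.86 ± 0.808 FPKM (log2 change 3.78, SE 0.126, adjusted p = 0.000226; n = 2 per group). IL33, an alarmin released by damaged epithelium, rose from 2.484 ± 0.608 to 32.33 ± 1.97 FPKM (3.27, SE 0.124, adjusted p = 0.000226). TNFRSF11B, the decoy receptor osteoprotegerin, rose by 2.28 (SE 0.102, adjusted p = 0.000306), and CLDN1, a tight junction protein, by 1.62 (SE 0.117, adjusted p = 0.00113). CXCL8, the neutrophil attractant, rose by 1.60 (adjusted p = 0.00176) and the immediate early factors EGR1 and JUN by 1.17 (SE 0.0754, adjusted p = 0.000738) and 0.95 (SE 0.0494, adjusted p = 0.000354). DDC, which makes dopamine and serotonin, fell from 65.68 ± 0.138 to 17.65 ± 1.65 FPKM (-1.84, SE 0.0759, adjusted p = 0.000231). AKR1B10, an aldo-keto reductase, fell from 21.53 ± 1.32 to 6.027 ± 0.245 FPKM (-1.68, SE 0.0579, adjusted p = 0.000226). The kinase-linked division genes CCNB2 and CDC25C fell by 0.72 (SE 0.0713, adjusted p = 0.00246) and by 0.80 (SE 0.0816, adjusted p = 0.00271).

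Of 12095 genes tested with limma in SNU719, 2737 changed (972 higher, 1765 lower); with the replicate block the count was 4856. The share higher was 35.5 percent, against 49.5 percent after median-of-ratios scaling and 47.1 percent after quantile normalization, so the excess of falls depends on the scaling. Without siCtrl 1, siCtrl 2, siMYB 1 or siMYB 2 of SNU719 the count was 1289, 1113, 1313 or 1417. Among lists, G1/S genes had 29 of 42 lower and 0 higher (32 lower adjusted over the list alone; median -0.36, adjusted p = 3.9e-09, adjusted p = 0.127 with an estimated correlation). G2/M genes had 35 of 50 lower (42 adjusted over the list alone; median -0.40, adjusted p = 8.83e-13, adjusted p = 0.139 with an estimated correlation). Immediate early genes had 8 of 16 higher and 0 lower (9 adjusted over the list alone; median 0.34, adjusted p = 8.88e-08, adjusted p = 0.127 with an estimated correlation). Epithelial genes had 11 of 27 higher and 4 lower (11 and 5 adjusted over the list alone; median 0.23, adjusted p = 0.000512, adjusted p = 0.139 with an estimated correlation). Gastric markers had 4 of 10 higher (4 adjusted over the list alone, with 1 lower; adjusted p = 0.00427, adjusted p = 0.227 with an estimated correlation). Cholesterol genes had 10 of 24 lower and 1 higher (16 and 1 adjusted over the list alone; adjusted p = 0.00188, adjusted p = 0.139 with an estimated correlation), and nucleolar genes 10 of 38 lower (11 adjusted over the list alone; adjusted p = 0.00284, adjusted p = 0.227 with an estimated correlation). Apoptosis regulators had 6 of 22 higher and 1 lower (7 and 2 adjusted over the list alone; adjusted p = 0.0136, adjusted p = 0.139 with an estimated correlation). WNT targets had 7 of 22 higher and 4 lower (9 and 6 adjusted over the list alone; adjusted p = 0.0481, adjusted p = 0.196 with an estimated correlation), and the list call was lost with the block (0.0731) and after either scaling (0.0808 and 0.11). Oxidative phosphorylation genes did not pass (7 of 38 lower, 7 adjusted over the list alone, adjusted p = 0.0819), and passed with the block (0.0491) and after quantile normalization (0.0484). For the stress response and antigen presentation the median and mean were negative and the test pointed up; for NF-kB genes only the median was negative.

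The same question was asked in YCC10, where MYB fell further; whether the changes follow from that fall was not tested. LEMD1, a cancer-testis antigen, rose from 2.538 ± 0.539 to 37.6 ± 2.76 FPKM (3.45, SE 0.117, adjusted p = 9.45e-05; n = 2 per group). MMP7, the epithelial matrix protease matrilysin, rose from 87.3 ± 1.5 to 444.3 ± 1.68 FPKM (2.33, SE 0.162, adjusted p = 0.000383). CD74, the invariant chain of MHC class II, rose from 1.855 ± 0.202 to 10.89 ± 0.332 FPKM (2.06, SE 0.09, adjusted p = 0.00015) with its activator CIITA (1.20, SE 0.0965, adjusted p = 0.000575). PGC, the pepsinogen of gastric chief cells, rose from 19.62 ± 0.982 to 70.72 ± 1.62 FPKM (1.80, SE 0.0646, adjusted p = 0.00011), while TFF1, a mucus peptide of surface cells, fell by 1.41 (adjusted p = 0.00441). LPXN, an adaptor of focal adhesions, fell from 27.17 ± 0.953 to 3.253 ± 0.333 FPKM (-2.73, SE 0.0772, adjusted p = 9.45e-05) and RAB8A, a small GTPase of secretion, from 53.71 ± 1.37 to 8.069 ± 0.366 FPKM (-2.59, SE 0.069, adjusted p = 9.45e-05). LCK, a T-cell kinase also present in this line, fell from 14.2 ± 1.21 to 2.419 ± 0.0829 FPKM (-2.15, SE 0.0994, adjusted p = 0.000152). In its 3' UTR LPXN holds 4 of the 7-mers tied to siMYB, RAB8A holds 2 and LCK holds 0. TYMS, which makes thymidylate, fell by 1.30 (SE 0.0435, adjusted p = 9.45e-05), and CDCA3, a trigger of mitotic entry, by 1.41 (SE 0.108, adjusted p = 0.000504). NOB1, a nuclease that finishes 18S rRNA, fell by 1.13 (SE 0.0699, adjusted p = 0.000287).

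In YCC10 5056 of 12095 genes changed (1851 higher, 3205 lower). The share higher was 36.6 percent, against 50.8 percent after median-of-ratios scaling and 50.3 percent after quantile normalization. G1/S genes had 38 of 42 lower (39 adjusted over the list alone; median -0.71, adjusted p = 2.42e-13, adjusted p = 0.0968 with an estimated correlation). G2/M genes had 47 of 50 lower (49 adjusted over the list alone; median -0.60, adjusted p = 2.42e-13, adjusted p = 0.202 with an estimated correlation). Nucleolar genes had 30 of 38 lower and 1 higher (32 and 2 adjusted over the list alone; median -0.47, adjusted p = 4.15e-07, adjusted p = 0.202 with an estimated correlation). Antigen presentation had 11 of 18 higher and 3 lower, the same adjusted over the list alone (median 0.43, adjusted p = 0.000219, adjusted p = 0.517 with an estimated correlation). Cholesterol genes had 15 of 24 lower (16 adjusted over the list alone; median -0.41, adjusted p = 0.0024, adjusted p = 0.202 with an estimated correlation). Ribosomal proteins had 15 of 67 lower and 1 higher (11 and 1 adjusted over the list alone) and did not pass (adjusted p = 0.0596; 0.00131 with the block). WNT targets, apoptosis regulators and intestinal markers had a negative median with a positive mean and test, and the stress response a negative median and mean with a test pointing up.

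Over both lines the question is which siMYB effects are shared. SULT1E1, which inactivates estrogens, rose by 2.26 (SE 0.081, adjusted p = 0.000138; n = 4 per group), and LEMD1 rose by 2.99 (SE 0.193, adjusted p = 0.000629). SPINK4, a goblet-cell peptide, rose by 1.86 (SE 0.148, adjusted p = 0.00105), and TNFSF15, a cytokine acting on T cells and endothelium, by 1.75 (SE 0.195, adjusted p = 0.00216). BMP4, a secreted differentiation signal, rose by 1.59 (SE 0.0939, adjusted p = 0.000434) from 2.746 to 10.06 FPKM in SNU719 and from 0.9772 to 5.134 FPKM in YCC10. MCL1, which blocks mitochondrial apoptosis, rose by 1.02 (SE 0.0784, adjusted p = 0.000978), and CLDN1 by 1.18 (SE 0.188, adjusted p = 0.00642). AKR1B10 fell by 1.96 (SE 0.116, adjusted p = 0.000434), DDC by 1.59 (SE 0.11, adjusted p = 0.000757) and EI24, an endoplasmic reticulum protein induced by p53, by 1.65 (SE 0.154, adjusted p = 0.0015). CDC25C, the phosphatase that starts mitosis, fell by 0.92 (SE 0.0744, adjusted p = 0.00113), and CDT1, which licenses replication origins, by 0.91 (SE 0.106, adjusted p = 0.00243). INSIG1, a sterol-regulated brake on cholesterol synthesis, fell by 0.88 (SE 0.0896, adjusted p = 0.0018). USP18, which restrains interferon signaling, gave -1.29 (adjusted p = 0.000434), while IFI6, an interferon-induced mitochondrial protein, rose by 1.12 (adjusted p = 0.0155). Of the 10 largest falls under the naming rule, AKR1B10 and MYB itself among them, 9 hold a 7-mer tied to siMYB in the 3' UTR (6 of 10 in SNU719, 7 of 10 in YCC10). Among the largest rises 3 of 9 searched hold one (2 of 9 in SNU719, 3 of 10 in YCC10), and 47.7 percent of all searched genes do. The 7-mers were chosen from the same fold changes, so high counts among the falls are built in.

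Over both lines 3561 genes changed (1060 higher, 2501 lower), and 1562 changed in the same direction in each line alone, against 216 in opposite directions. The share higher was 29.8 percent, against 48.8 percent after median-of-ratios scaling and 46.4 percent after quantile normalization. Without YCC10 siCtrl 1, siCtrl 2 or siMYB 1 of the MYB set the count was 2361, 1983 or 1993. G1/S genes had 36 of 42 lower (37 adjusted over the list alone; median -0.55, adjusted p = 2.11e-12, adjusted p = 0.332 with an estimated correlation). G2/M genes had 47 of 50 lower (49 adjusted over the list alone; median -0.50, adjusted p = 1.23e-16, adjusted p = 0.28 with an estimated correlation). Nucleolar genes had 25 of 38 lower and 1 higher (28 and 1 adjusted over the list alone; median -0.35, adjusted p = 1.13e-05, adjusted p = 0.554 with an estimated correlation). Cholesterol genes had 15 of 24 lower (16 adjusted over the list alone; median -0.38, adjusted p = 0.000119, adjusted p = 0.116 with an estimated correlation). Epithelial genes had 9 of 27 higher and 4 lower (11 and 4 adjusted over the list alone; adjusted p = 0.0285, adjusted p = 0.28 with an estimated correlation). Immediate early genes had 4 of 16 higher (5 adjusted over the list alone; adjusted p = 0.0164, adjusted p = 0.575 with an estimated correlation). Apoptosis regulators had 4 of 22 higher and 2 lower, the same adjusted over the list alone (adjusted p = 0.0465, adjusted p = 0.28 with an estimated correlation), and the call was lost after either scaling (0.0604 and 0.0603). Antigen presentation had 5 of 18 higher and 3 lower (6 and 3 adjusted over the list alone; adjusted p = 0.0422, adjusted p = 0.575 with an estimated correlation), and the call was lost with the block (0.0619) and after either scaling (0.145 and 0.154).

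The remaining lists did not pass over both lines. Known MYB targets had 3 of 19 higher and 6 lower (the same adjusted over the list alone, adjusted p = 0.378). WNT targets had 5 of 22 higher and 2 lower (6 and 2 adjusted over the list alone, adjusted p = 0.073) and p53 targets 6 of 26 higher and 8 lower (7 and 8 adjusted over the list alone, adjusted p = 0.363). Gastric markers had 2 of 10 higher (4 higher and 1 lower adjusted over the list alone, adjusted p = 0.0629). The stress and unfolded protein responses had 9 of 30 higher and 8 lower (9 and 9 adjusted over the list alone, adjusted p = 0.82): PDIA4, a folding enzyme, rose by 1.31 (adjusted p = 0.0148), and PSAT1, of serine synthesis, fell by 1.13 (adjusted p = 0.00318). Interferon genes (adjusted p = 0.971), NF-kB genes (adjusted p = 0.971), mesenchymal genes (adjusted p = 0.321), intestinal markers (adjusted p = 0.478), stem markers (adjusted p = 0.164), hypoxia genes (adjusted p = 0.904), oxidative phosphorylation (adjusted p = 0.971) and non-polyadenylated histones (adjusted p = 0.247) gave no call. Ribosomal proteins did not pass (11 of 67 lower, 9 adjusted over the list alone, adjusted p = 0.0551; 0.00975 with the block). For p53 targets the median was negative and the mean and test positive; for the stress response and NF-kB genes the median and mean were negative and the test pointed up. Among lists too small to test, CD68, a lysosomal marker of macrophages in the lymphoid list, rose by 0.45 (adjusted p = 0.00751), and ESAM, an endothelial adhesion protein, fell by 0.62 (adjusted p = 0.0149). The mitochondrially encoded list had 0 tested members.

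**Figure D2:**
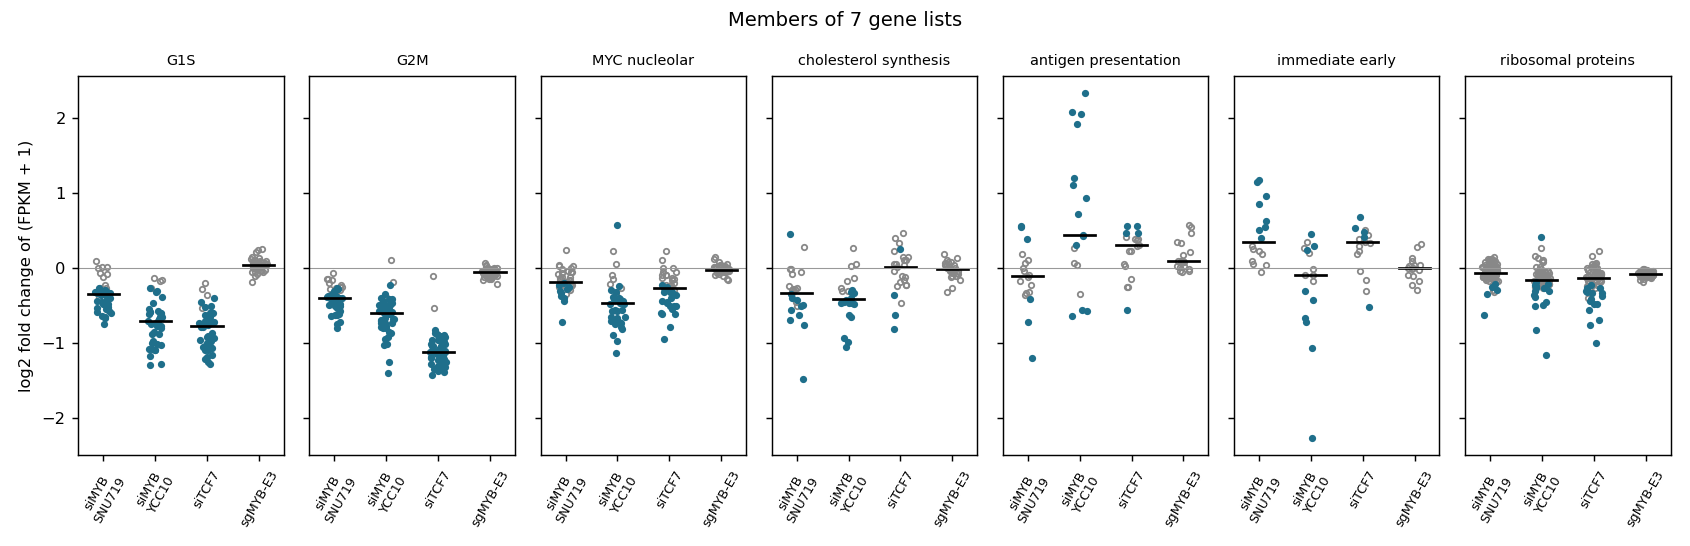
Log2 changes of the members of 7 gene lists in the tested comparisons. Filled dots passed the threshold, open dots did not, and bars are medians.

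Whether the siMYB effect differs between the lines was tested directly. REG4, a secreted growth factor of the gut, rose in SNU719 from 151.7 ± 1.55 to 315.9 ± 11.7 FPKM and fell in YCC10 from 46.43 ± 2.81 to 11.84 ± 0.684 FPKM (difference 2.94, SE 0.094, adjusted p = 0.000333; n = 2 per group). ALDH1A1, an aldehyde dehydrogenase of retinoic acid synthesis, fell in SNU719 from 79.75 ± 3.28 to 26.73 ± 0.922 FPKM and rose in YCC10 from 44.21 ± 1.91 to 166.2 ± 4.41 FPKM (difference -3.43, SE 0.0836, adjusted p = 0.00016). EGR1 rose by 1.17 in SNU719 and fell by 0.67 in YCC10 (difference 1.84, SE 0.107, adjusted p = 0.00111). CAPN8, a gastric calpain, rose by 0.64 in SNU719 and fell by 0.87 in YCC10 (difference 1.51, SE 0.116, adjusted p = 0.00191). LCK gave 0.12 in SNU719 (adjusted p = 0.424) and -2.15 in YCC10 (difference 2.27, SE 0.141, adjusted p = 0.00116). CD74 gave -0.04 in SNU719 (adjusted p = 0.808) and 2.06 in YCC10 (difference -2.10, SE 0.127, adjusted p = 0.00116).

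In this test 2297 genes differed (1251 with the higher change in SNU719, 1046 in YCC10); with the replicate block the count was 4352. Leaving out any 1 of the 8 libraries gave 972 to 1418. Of the differing genes 54.5 percent had the higher change in SNU719; it was 43.1 percent after quantile normalization. G1/S genes had 17 members falling further in YCC10 and 0 the other way (22 adjusted over the list alone; median 0.35, adjusted p = 6.94e-07, adjusted p = 0.206 with an estimated correlation). G2/M genes had 9 and 0 (7 and 0 adjusted over the list alone; median 0.22, adjusted p = 0.000259, adjusted p = 0.441 with an estimated correlation), and nucleolar genes 12 and 1 (14 and 1 adjusted over the list alone; median 0.27, adjusted p = 1.54e-05, adjusted p = 0.245 with an estimated correlation). Immediate early genes had 10 members with the higher change in SNU719 and 0 lower (11 adjusted over the list alone; median 0.48, adjusted p = 8.81e-06, adjusted p = 0.206 with an estimated correlation). Antigen presentation had 8 members with the higher change in YCC10 (10 adjusted over the list alone; median -0.40, adjusted p = 2.65e-05, adjusted p = 0.405 with an estimated correlation). Oxidative phosphorylation had 5 (3 adjusted over the list alone; median -0.16, adjusted p = 0.000719, adjusted p = 0.526 with an estimated correlation). Interferon genes had 1 higher and 4 lower of 20 (2 and 6 adjusted over the list alone; median -0.23, adjusted p = 0.0251, adjusted p = 0.4 with an estimated correlation), and the call was lost after median-of-ratios scaling (0.0584). Stem markers had 4 lower of 15, the same adjusted over the list alone (median -0.14, adjusted p = 0.0438, adjusted p = 0.405 with an estimated correlation), and the call was lost with the block (0.102) and after either scaling (0.0584 and 0.0646). Ribosomal proteins passed only with the block (0.0477 against 0.247). The p53 targets did not pass in the main list test and passed after quantile normalization (0.0461). For WNT targets the median was negative with a positive mean and test, and for intestinal markers the median and mean were positive and the test pointed down.

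For siTCF7 the question is which genes change over both lines. IL1RN, the interleukin-1 receptor antagonist, rose from 3.273 to 13.29 FPKM in SNU719 and from 10.66 to 33.47 FPKM in YCC10 (1.65, SE 0.118, adjusted p = 0.000624; n = 1 per group and line). SPRR3 rose from 1.046 to 4.873 FPKM in SNU719 and from 32.08 to 281.4 FPKM in YCC10 (2.31, SE 0.304, adjusted p = 0.00503). TSPAN1, an epithelial tetraspanin, rose by 1.79 (SE 0.167, adjusted p = 0.00178), CLDN1 by 1.46 (SE 0.16, adjusted p = 0.00271) and CEACAM6, an intestinal adhesion antigen, by 1.41 (SE 0.279, adjusted p = 0.013). KIF20A, a kinesin of cytokinesis, fell by 1.43 (SE 0.21, adjusted p = 0.00691), and CCNB2, a mitotic cyclin, by 1.37 (SE 0.203, adjusted p = 0.00699). CDCA7L, a MYC partner, fell by 1.55 (SE 0.154, adjusted p = 0.00206), and LAPTM4A, a lysosomal protein, by 1.62 (SE 0.146, adjusted p = 0.00162). NOP56, a core protein of nucleolar rRNA methylation, fell by 0.61 (adjusted p = 0.00372). TNFRSF19, a WNT-responsive receptor, fell by 0.76 (adjusted p = 0.00699). In SNU719 alone SPRR3 gave 1.52, CEACAM6 0.64, KIF20A -0.85 and CCNB2 -0.84, and in YCC10 alone CEACAM6 gave 2.17. Among the largest falls under the naming rule 7 of 9 searched hold a 7-mer tied to siTCF7, against 1 of 9 among the largest rises. Of all searched genes 40 percent hold one. These 7-mers were chosen from the same fold changes, so high counts among the falls are built in.

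For siTCF7 3028 of 12290 genes changed (1407 higher, 1621 lower), and with only the 4 libraries of the TCF7 set the count was 13. The share higher was 46.5 percent, against 50.5 percent after either scaling and 54.6 percent among genes without the siTCF7 7-mers. A fit without either YCC10 library of the TCF7 set holds the SNU719 effect alone and called fewer genes. The siTCF7 effects spread wider in YCC10 (SD of log2 changes 0.541) than in SNU719 (0.285). G1/S genes had 37 of 42 lower (41 adjusted over the list alone; median -0.77, adjusted p = 2.83e-15, adjusted p = 0.424 with an estimated correlation). G2/M genes had 48 of 50 lower (49 adjusted over the list alone; median -1.12, adjusted p = 3.26e-19, adjusted p = 0.424 with an estimated correlation). Nucleolar genes had 20 of 38 lower (25 adjusted over the list alone; median -0.26, adjusted p = 4.19e-08, adjusted p = 0.229 with an estimated correlation). Intestinal markers had 4 of 10 higher (6 adjusted over the list alone; median 0.61, adjusted p = 0.00875, adjusted p = 0.424 with an estimated correlation). Ribosomal proteins had 17 of 67 lower, the same adjusted over the list alone (median -0.14, adjusted p = 2.87e-06, adjusted p = 0.424 with an estimated correlation), and the call was lost after quantile normalization (0.196). Immediate early genes had 4 of 16 higher and 1 lower (5 and 2 adjusted over the list alone; adjusted p = 0.0365, adjusted p = 0.424 with an estimated correlation), and the call was lost with the block (0.0644). For epithelial genes and gastric markers the median was negative with a positive mean and test, for cholesterol genes the median was positive with a negative mean and test, and for NF-kB genes only the mean was negative.

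With sgMYB-E3 the question is whether interference at the enhancer moves genes beyond MYB. CREB3L1, a membrane-bound transcription factor of secretory cells, fell from 9.164 to 5.246 FPKM in SNU719 and from 19.14 to 11.56 FPKM in YCC10 (-0.69, SE 0.0642, adjusted p = 0.0163; n = 1 per group and line). That call was lost without YCC10 siCtrl 1 or siCtrl 2 of the MYB set, and without SNU719 siMYB 1 or siMYB 2. It was also lost with the effect of either line alone (-0.7025 in SNU719 and -0.6814 in YCC10). CREB3L1 gave 0.24 with siMYB over both lines (adjusted p = 0.0322). Other genes with low p did not pass: FGF20, a growth factor, had 11.62 against 4.57 FPKM in SNU719 and 8.571 against 4.326 FPKM in YCC10 (1.01, SE 0.115, adjusted p = 0.0504). LCK had 0.6377 against 1.886 FPKM in SNU719 and 8.442 against 14.92 FPKM in YCC10 (-0.79, SE 0.0909, adjusted p = 0.0504). Without short RNA genes in the fit FGF20 and LCK had adjusted p = 0.031 and 0.0432. TLN2, a talin linking integrins to actin, gave -0.42 (adjusted p = 0.0504), and LYZ, the lysozyme of gastric glands, -0.71 (adjusted p = 0.12).

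With sgMYB-E3 limma called 4 of 12290 genes (1 higher, 3 lower), and 461 had an unadjusted p under 0.05. The other called genes are the short RNAs SNORD24, SNORA54 and MIR4441, named here after their values were seen and not interpreted. With only the 4 libraries of the CRISPRi set the count was 13. It was 13 without any 1 library of the TCF7 set, where the line difference of siTCF7 leaves the shared spread. Without 1 CRISPRi library only the sgMYB-E3 effect of the other line remains, at 1 library per group. In the lists that follow 0 members passed, and 0 adjusted over the list alone. Ribosomal proteins had a median of -0.08 (adjusted p = 4.79e-10, adjusted p = 0.336 with an estimated correlation), NF-kB genes 0.16 (adjusted p = 0.000472, adjusted p = 0.336 with an estimated correlation) and antigen presentation 0.09 (adjusted p = 0.00181, adjusted p = 0.453 with an estimated correlation). The stress response had -0.12 (adjusted p = 0.00237, adjusted p = 0.417 with an estimated correlation), p53 targets 0.11 (adjusted p = 0.00256, adjusted p = 0.417 with an estimated correlation) and intestinal markers -0.13 (adjusted p = 0.0181, adjusted p = 0.417 with an estimated correlation). G1/S and G2/M genes did not pass (adjusted p = 0.324 and 0.194). Median, mean and test differed in sign for mesenchymal, epithelial, oxidative phosphorylation and immediate early genes.

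Which genes respond differently to siMYB and sgMYB-E3 was tested gene by gene. LPXN was lower after siMYB (-1.92, SE 0.0892, adjusted p = 8.07e-05), RAB8A gave -1.99 (SE 0.111, adjusted p = 0.000165) and EI24 -1.68 (SE 0.0731, adjusted p = 6.38e-05). TNFSF15 gave 1.61 (SE 0.118, adjusted p = 0.000704), and LEMD1 2.44 (SE 0.251, adjusted p = 0.00297). LPXN holds 4 of the 7-mers tied to siMYB, RAB8A 2, EI24 2, TNFSF15 2 and LEMD1 1. For the lower genes, direct seed repression was not separated from the fall of MYB. NOB1 gave -0.84 (SE 0.105, adjusted p = 0.00548). MYB itself gave -1.79 (SE 0.323, adjusted p = 0.0168). That call was lost with the sgMYB-E3 effect of either line alone (-1.494 for SNU719 and -2.095 for YCC10). In all, 1137 genes differed (353 higher, 784 lower after siMYB). The share higher was 31 percent, against 52.6 percent after median-of-ratios scaling and 51.7 percent after quantile normalization. The count fell without any 1 CRISPRi library, where the sgMYB-E3 effect is that of 1 line alone. It was 2455 to 2475 without any 1 library of the TCF7 set, and 627 to 731 without any 1 of the MYB set other than YCC10 siMYB 1.

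Lower after siMYB than after sgMYB-E3 were G1/S genes (4 members lower, 13 adjusted over the list alone; median -0.61, adjusted p = 4.2e-07, adjusted p = 0.657 with an estimated correlation). So were G2/M genes (0 members, 0 adjusted over the list alone; median -0.45, adjusted p = 0.000995, adjusted p = 0.781 with an estimated correlation). Nucleolar genes had 12 lower and 1 higher (21 and 1 adjusted over the list alone; adjusted p = 2.02e-06, adjusted p = 0.183 with an estimated correlation), and cholesterol genes 5 of 25 lower (12 adjusted over the list alone; adjusted p = 0.000869, adjusted p = 0.11 with an estimated correlation). Epithelial genes had 2 higher and 1 lower (7 and 3 adjusted over the list alone; adjusted p = 0.0293, adjusted p = 0.33 with an estimated correlation), gastric markers 1 higher (2 adjusted over the list alone; adjusted p = 0.0218, adjusted p = 0.33 with an estimated correlation) and immediate early genes 2 higher and 2 lower (3 and 2 adjusted over the list alone; adjusted p = 0.0218, adjusted p = 0.408 with an estimated correlation). Apoptosis regulators had 2 higher, the same adjusted over the list alone (adjusted p = 0.0447, adjusted p = 0.275 with an estimated correlation), and the call was lost after quantile normalization (0.0622). For stem markers, hypoxia genes and ribosomal proteins the median and mean were negative and the test pointed up.

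Which genes respond differently to siMYB and siTCF7 was tested in the same fit. H2BC12, a histone H2B, gave 2.73 (SE 0.261, adjusted p = 0.00144), LAPTM4A 2.16 (SE 0.179, adjusted p = 0.000949) and TXNIP, an inhibitor of thioredoxin, 2.09 (SE 0.213, adjusted p = 0.00182). CXCL5, a neutrophil attractant, gave 2.70 (SE 0.416, adjusted p = 0.00735), and 1.78 with the siTCF7 effect of SNU719 alone. AHCYL2, a regulator of ion transport, gave -1.96 (SE 0.101, adjusted p = 0.000148) and VILL, a villin relative, -1.98 (SE 0.156, adjusted p = 0.000774). LAPTM4A holds 4 of the 7-mers tied to siTCF7. CXCL5 holds 3 of those and 1 tied to siMYB, and AHCYL2 holds 4 tied to siMYB. For these genes direct seed repression was not separated from effects of the targets. TNFRSF19 gave 1.06 (SE 0.137, adjusted p = 0.00423) and HMGCS1, an early enzyme of cholesterol synthesis, -0.63 (SE 0.11, adjusted p = 0.0119). TCF7 gave 1.76 (adjusted p = 0.00125). MYB gave -1.39 (SE 0.323, adjusted p = 0.0304, and 0.0532 with the block). That call was lost without any 1 of the 8 MYB-set libraries and with the siTCF7 effect of YCC10 alone (-0.77). In all, 1618 genes differed (500 higher, 1118 lower after siMYB). The share higher was 30.9 percent, against 47.5 percent after median-of-ratios scaling and 45.9 percent after quantile normalization. The count rose with the siTCF7 effect of YCC10 alone and fell with that of SNU719 alone. It also fell without any 1 MYB-set library.

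G2/M genes were higher after siMYB than after siTCF7 (0 members passing, 0 adjusted over the list alone; median 0.58, adjusted p = 3.66e-11, adjusted p = 0.568 with an estimated correlation), as were G1/S genes (0 members, 0 adjusted over the list alone; median 0.23, adjusted p = 0.000327, adjusted p = 0.753 with an estimated correlation). WNT targets had 7 higher and 2 lower (7 and 3 adjusted over the list alone; median 0.13, adjusted p = 0.00478, adjusted p = 0.196 with an estimated correlation), and cholesterol genes 10 of 25 lower, the same adjusted over the list alone (median -0.33, adjusted p = 0.00478, adjusted p = 0.196 with an estimated correlation). Ribosomal proteins had 4 of 67 higher and 1 lower (3 and 1 adjusted over the list alone; median 0.02, adjusted p = 0.0303, adjusted p = 0.568 with an estimated correlation), and after quantile normalization the call was lost and the median turned negative (-0.02, adjusted p = 0.806). Mesenchymal genes and intestinal markers did not pass (adjusted p = 0.0594 each), and passed after median-of-ratios scaling (0.031 and 0.0309) and quantile normalization (0.0296 each). For nucleolar, stress response, epithelial, hypoxia and oxidative phosphorylation genes the median and mean were negative and the test pointed up; NF-kB and antigen presentation genes had a negative median with a positive mean.

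Whether the knockdowns move the same genes was described by correlation over 11769 genes without short RNAs; genes are not independent replicates. The siMYB and siTCF7 effects correlated at 0.484 in SNU719 and 0.449 in YCC10, and the siMYB and sgMYB-E3 effects at 0.346 and 0.0847. Between the lines the effects correlated at 0.439 for siMYB, 0.609 for siTCF7 and 0.206 for sgMYB-E3. Over both lines and all 12290 genes the values were 0.193 for siTCF7 and 0.0599 for sgMYB-E3. Of genes tested in both fits, 433 rose with both siRNAs (122 expected from the totals) and 923 fell with both (336 expected). Genes called in opposite directions numbered 43 (141 expected) and 97 (291 expected).

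**Figure D3:**
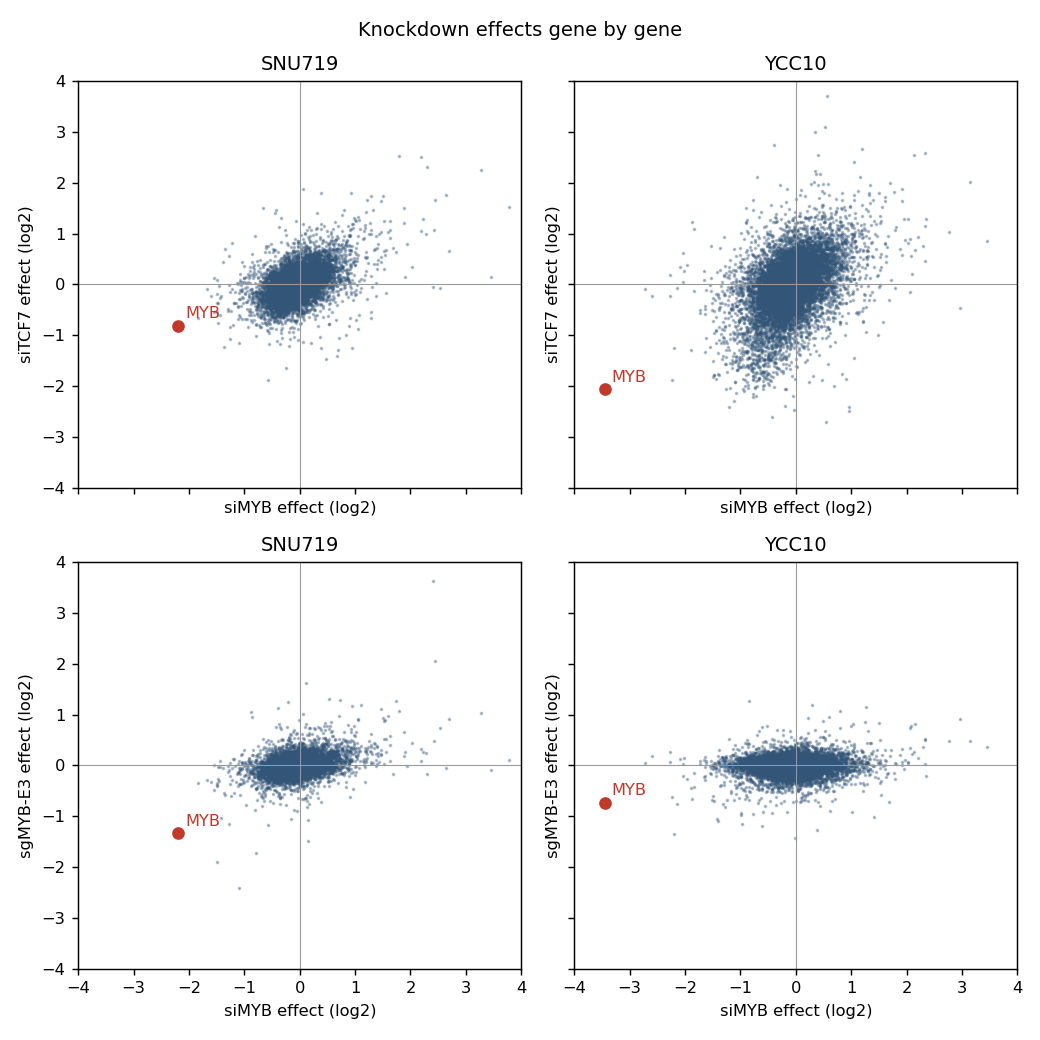
Log2 changes with siMYB against those with siTCF7 and with sgMYB-E3 in each line, for genes without short RNAs. Each dot is 1 gene.

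The last question is how the lines differ before knockdown, from 4 control libraries per line, with values given as SNU719 minus YCC10. Of the gastric markers, MUC1, a surface mucin, gave -4.54 (SE 0.0966, adjusted p = 5.17e-07), PGC -4.43 (SE 0.0816, adjusted p = 3.4e-07) and TFF1 -4.04 (SE 0.25, adjusted p = 3.12e-05). Of the intestinal markers, CDH17, a liver-intestine cadherin, gave 5.20 (SE 0.126, adjusted p = 8.12e-07) and VIL1, the brush-border villin, 3.69 (SE 0.081, adjusted p = 5.52e-07), while TFF3, a goblet-cell peptide, gave -3.90 (SE 0.382, adjusted p = 0.00023). HSPB1, a small heat shock protein, had 268.7 to 720.2 FPKM in SNU719 and was listed at 0 in 4 of 4 YCC10 libraries. DKK1, a WNT antagonist, was listed at 0 in 4 of 4 SNU719 libraries and had 146.3 to 214.3 FPKM in YCC10. These zeros may be failures of quantification rather than absence of RNA, since broadly used genes are also listed at 0: PARK7, a redox chaperone, in 4 of 4 SNU719 libraries (171.5 to 235.8 FPKM in YCC10) and ESD, an esterase, in 4 of 4 YCC10 libraries (79.89 to 120.6 FPKM in SNU719). ODAM, an epithelial secreted protein, had 0.3315 to 0.513 FPKM in SNU719 and 362.1 to 577 FPKM in YCC10, and CXCL13, a B-cell attractant, 0.1646 to 0.5309 and 138.3 to 298.5 FPKM. GAGE10, a cancer-testis antigen, had 162.8 to 210.5 FPKM in SNU719 and was listed at 0 in 4 of 4 YCC10 libraries, but its family members share sequence, so the assignment is uncertain. MYB was higher in SNU719 (0.81, SE 0.0928, adjusted p = 0.000472), as was TCF7 (0.35, SE 0.0746, adjusted p = 0.00658).

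In the controls 7797 of 12187 genes differed (4089 higher in SNU719, 3708 higher in YCC10), and the gene calls carry the medium of each line as well as the line. Gastric markers had 9 of 10 lower in SNU719 and 1 higher (median -3.06, adjusted p = 0.000662, adjusted p = 0.487 with an estimated correlation), and intestinal markers 8 of 10 higher and 2 lower (median 1.37, adjusted p = 0.0165, adjusted p = 0.487 with an estimated correlation). G2/M genes had 29 of 50 lower and 3 higher (adjusted p = 0.000662, adjusted p = 0.666 with an estimated correlation), oxidative phosphorylation 21 of 38 lower and 2 higher (adjusted p = 0.000662, adjusted p = 0.652 with an estimated correlation), and immediate early genes 9 of 16 lower and 1 higher (adjusted p = 0.0165, adjusted p = 0.487 with an estimated correlation). Interferon genes had 15 of 20 higher and 3 lower (median 0.56, adjusted p = 0.0165, adjusted p = 0.552 with an estimated correlation). Calls lost after quantile normalization were known MYB targets (10 of 19 lower and 3 higher, adjusted p = 0.0376, 0.0672 after it, adjusted p = 0.487 with an estimated correlation) and p53 targets (14 of 26 lower and 2 higher, adjusted p = 0.0232, 0.0533 after it, adjusted p = 0.552 with an estimated correlation). The same holds for nucleolar genes (19 of 38 lower and 5 higher, adjusted p = 0.0463, 0.172 after it, adjusted p = 0.652 with an estimated correlation) and the stress response (14 of 30 lower and 2 higher, adjusted p = 0.0463, 0.114 after it, adjusted p = 0.652 with an estimated correlation). Counts adjusted over the list alone were the same for these lists, except 18 lower for nucleolar genes. Median, mean and test differed in sign for WNT targets, G1/S genes, cholesterol genes and ribosomal proteins.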

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

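The tests of the difference between the lines were chosen before the data were examined, and which list members are given was decided after results were seen. Every value in this part is the siMYB effect in SNU719 minus that in YCC10, set apart by a test of the difference itself with limma (n = 2 per group and line). In all 2297 genes differed. No explanation of the difference was tested.

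The target itself differed: MYB fell further in YCC10 (difference 1.26, adjusted p = 0.00671). SPRR3 rose in both lines and differed by 3.24 (adjusted p = 0.00103). IL33 rose in SNU719 and differed by 3.24 (adjusted p = 0.00102), with both YCC10 siCtrl libraries listed at 0. IGFL1, a growth factor of skin, differed by 3.12 (adjusted p = 0.00195) and WFDC3, a protease inhibitor, by 2.77 (adjusted p = 0.00195). TNFRSF11B was listed at 0 in all YCC10 libraries of the set. Its difference of 2.28 (adjusted p = 0.0012) therefore only restates the rise in SNU719 and cannot show a difference between the lines. LCK (2.27, adjusted p = 0.00116) and FOSL1, an AP-1 factor (2.21, adjusted p = 0.00128), fell only in YCC10.

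Opposite directions past the threshold in each line were found for TNS4, a focal adhesion tensin (difference 2.98, adjusted p = 0.000835), REG4 (2.94, adjusted p = 0.000333) and CXCL8 (2.57, adjusted p = 0.00191). The alcohol dehydrogenase ADH6 (-2.05, adjusted p = 0.00128) and ALDH1A1 (-3.43, adjusted p = 0.00016) fell in SNU719 and rose in YCC10. Rises confined to YCC10 were found for REG1A, a regenerating islet lectin (-3.91, adjusted p = 0.0036), PCP4, a calmodulin regulator (-3.15, adjusted p = 0.000957), and LOXL1, which crosslinks elastin (-2.47, adjusted p = 0.00138). The same holds for ADH1C, an alcohol dehydrogenase (-2.31, adjusted p = 0.00116), HABP2, a plasma protease (-2.29, adjusted p = 0.00103), and CD74 (-2.10, adjusted p = 0.00116). FDCSP, a secreted peptide (-2.30, adjusted p = 0.00128), and SERPINA3, an acute-phase protease inhibitor (-2.07, adjusted p = 0.00116), rose in YCC10 and were listed at 0 in all SNU719 libraries of the set. For both genes the value only restates the rise in YCC10 and cannot show a difference between the lines.

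Among lists, G1/S genes (median 0.35), G2/M genes (0.22) and nucleolar genes (0.27) fell further in YCC10, with 17 of 42, 9 of 50 and 12 of 38 members passing. With an estimated correlation these calls were lost (adjusted p = 0.206, 0.441 and 0.245). CCNE2, a cyclin of S-phase entry, differed by 1.02 (adjusted p = 0.00967) and RRM2, of ribonucleotide reductase, by 0.83 (adjusted p = 0.00463). DDX21, a nucleolar helicase, differed by 0.80 (adjusted p = 0.00902; 0.0583 after quantile normalization). HMMR, a spindle protein, differed by 0.82 (adjusted p = 0.0492) and lost its call after median-of-ratios scaling (0.0695), after quantile normalization (0.114) and without any 1 library other than SNU719 siCtrl 1 (0.0642 to 0.144). CDCA3 differed by 0.66 (adjusted p = 0.0358) and lost its call without any 1 of the 8 libraries (0.0525 to 0.107). MYBBP1A, a nucleolar partner of MYB, differed by 0.73 (adjusted p = 0.0221) and lost its call without any 1 library other than YCC10 siCtrl 1 and YCC10 siMYB 2 (0.0506 to 0.0739).

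Antigen presentation (median -0.40), interferon genes (-0.23), stem markers (-0.14) and oxidative phosphorylation (-0.16) lay higher in YCC10, with 8 of 18, 4 of 20, 4 of 15 and 5 of 38 members passing that way. With an estimated correlation these calls were lost (adjusted p = 0.405, 0.4, 0.405 and 0.526). Interferon genes also lost the call after median-of-ratios scaling (0.0584), and stem markers with the block (0.102) and after either scaling (0.0584 and 0.0646). CIITA differed by -1.20 (adjusted p = 0.00512), EPSTI1, an interferon-induced protein, by -1.07 (adjusted p = 0.00509) and LGR5, a stem-cell receptor, by -1.10 (adjusted p = 0.00475). The succinate dehydrogenase subunits SDHA (-0.61, adjusted p = 0.00471) and SDHC (-0.55, adjusted p = 0.00823) rose only in YCC10. Immediate early genes lay higher in SNU719 (median 0.48; adjusted p = 0.206 with an estimated correlation), with EGR1 at 1.84 (adjusted p = 0.00111).

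List members past the threshold in each line in opposite directions rose in SNU719 and fell in YCC10. They were OASL, an antiviral protein (1.26, adjusted p = 0.00191), ETS2, a RAS-responsive factor (0.98, adjusted p = 0.00128), and GADD45A, a growth arrest gene (0.55, adjusted p = 0.00475). Among stress and death genes were PMAIP1, the killer NOXA (1.5, adjusted p = 0.00206), SLC7A11, the cystine transporter (1.91, adjusted p = 0.00333), and TNFAIP3, a brake on NF-kB (0.72, adjusted p = 0.0068). KRT18, a simple epithelial keratin, differed by 1.45 (adjusted p = 0.000739); its YCC10 call was lost after quantile normalization (-0.50, 0.0644). KRT8, its partner keratin, differed by 1.19 (adjusted p = 0.0014), and by 0.66 after quantile normalization (adjusted p = 0.13). CAPN8 differed by 1.51 (adjusted p = 0.00191). LGR5 ran the other way, lower in SNU719 (-0.36, adjusted p = 0.0326) and higher in YCC10 (0.74, adjusted p = 0.00167).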

How the results depend on the processing

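The alternatives below were chosen before the data were examined, with some exceptions. The libraries numbered 2, genes without 7-mers, single-row symbols, no short RNA genes and scaling in the list tests were chosen after seeing the data. Where a cause is not given, the cause was not tested. Of the named gene results 0 were reversed. Among lists past the threshold, the median of the ribosomal proteins in siMYB minus siTCF7 turned negative after quantile normalization (-0.02).

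With same-numbered pairs within a line as blocks, siMYB called 4856 genes in SNU719 and 4352 in the line difference. The block also ended 4 list calls, added 4 and ended 44 named gene calls; the other calls of genes named and lists tested were the same. Among genes without the siMYB 7-mers siMYB called 1401 in SNU719, 2463 in YCC10 and 1757 over both lines, and among genes without the siTCF7 7-mers siTCF7 called 1858, since fewer genes were tested. With only the libraries numbered 2, siMYB over both lines called 8, with fewer samples. With only the 4 libraries of the set, siTCF7 called 13 and sgMYB-E3 called 13. For sgMYB-E3 no filter gave 8, a filter of 5 FPKM gave 2 and single-row symbols gave 2.

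Leaving out each library in turn gave 1113–2323 genes for siMYB in SNU719, 1983–3065 over both lines and 972–1418 for the line difference. For siTCF7 it gave 630–4307, for sgMYB-E3 3–40, for siMYB minus sgMYB-E3 150–2475, and for siMYB minus siTCF7 982–3248. Counts moved by more than 1.5 times without any SNU719 library for siMYB in SNU719 (1289, 1113, 1313, 1417) and without YCC10 siCtrl 1 (2361), siCtrl 2 (1983) or siMYB 1 (1993) over both lines. The line difference moved without each of the 8 libraries, and siTCF7 without either YCC10 library of its set. Without 1 library of its own set, siTCF7 or sgMYB-E3 is left with its effect in the other line alone. Counts from these fits therefore reflect lines rather than single libraries. For sgMYB-E3 the count was 13 without any TCF7-set library and 31 to 40 without any CRISPRi library. For siMYB minus sgMYB-E3 it was 150 to 257 without any CRISPRi library, 2455 to 2475 without any TCF7-set library and 627 to 731 without any MYB-set library but YCC10 siMYB 1. For siMYB minus siTCF7 it was 3248 without either SNU719 and 1003 without either YCC10 TCF7-set library, and 982 to 1027 without any MYB-set library but YCC10 siMYB 2.

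The correlation of siMYB and sgMYB-E3 effects over both lines (0.0599) was 0.176 by Spearman, 0.311 over called genes and 0.26 without short RNA genes. For siMYB and siTCF7 (0.193) it was 0.123 with a pseudocount of 0.1, 0.173 at 5 FPKM, 0.442 by Spearman, 0.508 over called genes and 0.492 without short RNA genes. Of 65 gene list calls 0 remained with an estimated correlation. Of 16435 alternatives for named genes, 14705 were the same, 1692 weaker and 38 stronger.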

Other observations

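The searches for seed matches, the tests on genes without them and the other splits of the libraries were chosen before the data were examined; the tests on the number of libraries and on the fall of MYB were chosen after seeing the results.

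Some named genes that changed were not described so far. In SNU719 PHGDH, the first enzyme of serine synthesis, fell by 1.30 (adjusted p = 0.000493), and SLC2A3, a glucose transporter, rose by 1.89 (adjusted p = 0.000319). In YCC10 LDHA, which makes lactate, fell by 0.99, and BMF, a BCL2-family killer, rose by 1.71 (adjusted p = 0.000196). With siTCF7 PI3, an elastase inhibitor of inflamed epithelium, rose from 29.05 to 172.9 FPKM in SNU719 and from 5.701 to 15.73 FPKM in YCC10 (1.93, SE 0.342, adjusted p = 0.0104).

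Both siRNAs changed many genes and sgMYB-E3 called 4, which may partly reflect siRNA seed matches. Among 3' UTR 7-mers, 4 met the written condition for siMYB and 6 for siTCF7, and none passed for sgMYB-E3. This met the condition written for seed matches, although the siRNA sequences are not given in the sources used here. The condition written against direct seed repression as the whole cause was met. Of the searched genes without a siMYB 7-mer 30.1 percent still passed for siMYB over both lines, against 33 percent of those with one. Of the genes without one 10.4 percent rose, which argues against direct repression as the whole cause. Falls alone were 19.7 against 25 percent, and in YCC10 23.4 against 34.1 percent. The falls cannot decide, since only the 4 kept 7-mers were excluded. Others past Bonferroni correction remain, such as AAGGAAT in YCC10 (t = -7.392), and the shares were not adjusted for UTR length. With as many libraries in the same fit siTCF7 called 3028 genes, which met the condition set against too few libraries. Simulation with 1 effect shared by both lines recovered 87 percent of 2-fold changes for sgMYB-E3 and 44 percent at 1.5-fold. Yet MYB itself gave -1.03 with sgMYB-E3 and did not pass in limma (adjusted p = 0.981). That p also carries the line difference of siTCF7, through the shared spread. The siTCF7 effects also spread wider (SD of log2 changes 0.541 against 0.153 in YCC10, 0.285 against 0.164 in SNU719). Too few libraries therefore cannot be excluded, even for large changes. With only the 4 libraries of the set siTCF7 and sgMYB-E3 called 13 each, so smaller effects may be missed. Effects in proportion to the fall of MYB are argued against for the siMYB changes as a whole: the slopes of sgMYB-E3 on siMYB effects were 0.183 in SNU719 and 0.0257 in YCC10, while the log2 fall of MYB with sgMYB-E3 was 0.607 and 0.211 of that with siMYB, a gap beyond the largest replicate slope of 0.0477 in both lines, though with 1 library per group; proportional effects among the MYB-driven changes alone, or a threshold, stay open.

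The effects of siTCF7 ran with those of siMYB, and this could come from seed matches shared by both siRNAs or from the fall of MYB after siTCF7. Over 4195 searched genes with no 7-mer of either siRNA the correlation was 0.579 in SNU719 and 0.525 in YCC10. These genes were chosen to hold none of the 7-mers, so the value only shows that the correlation persists without such matches. GAAGACA, the top 7-mer of siTCF7, had a positive t with siMYB (3.095 in SNU719 and 3.288 in YCC10). AAAGGAA, the top 7-mer of siMYB, had -1.729 and -0.619 with siTCF7, short of Bonferroni correction. Matches to other 7-mers were not excluded. In SNU719 sgMYB-E3 lowered MYB more than siTCF7 did, yet the siTCF7 slope on siMYB effects exceeded the sgMYB-E3 slope by 0.292, with 1 library per group. The siTCF7 slopes over searched genes without a siMYB 7-mer lay above the MYB ratios, 0.475 against 0.37 in SNU719 and 0.643 against 0.594 in YCC10. This YCC10 gap lies within 2 times the replicate slope of 0.0477. Over called genes the slopes lay further above the ratios (0.516 and 0.796), but the condition was not written for these genes. By SNU719 alone the explanation would be ruled out. The condition on YCC10 was added after these values were seen, and the explanation is left open. A shared response to siRNA transfection, slower division after either siRNA and a common program of both factors were not separated here.

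Other ways of splitting the libraries were counted. In every other split the real effect stays in the residual spread and lowers the count, so these counts cannot exclude chance. In each comparison 1 split could not be fitted and is left out. For siMYB over both lines the real split called 3561 genes, and 1 of 34 splits, the real one, reached that count; the highest other, which parts the libraries by replicate number, called 52. Of the 8 splits that part every pair of same-numbered libraries, the highest other called 49. For the control libraries the real split by line called 7797 genes, and 1 of 34 splits, the real one, reached it; the highest other called 26.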
